A study of Homo sapiens with 8 samples.

How the data were processed

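Chromatin from sorted tonsil CD4 T cells was cross-linked with formaldehyde, sheared by sonication and immunoprecipitated with antibodies against H3K4me1, H3K27Ac and H3K27me3, per the labels' protocols. The 8 samples comprise 1 library per cell type and mark and a library labelled TI for each cell type. The labels do not say how many donors contributed. Genome build hg19 and the tools CASAVA 1.8.2, BWA 0.6.1 and MACS2 2.0.10.20131216 are named in the submitters' processing notes, without the role or settings of each. The 6 peak lists, 1 per cell type and mark, were used as deposited.

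For the 4 H3K27Ac and H3K4me1 lists, the deposited value per peak is a score with a minimum of 50 and a maximum of 3233, and how it was computed is not given in the sources used here. It resembles the score of an older MACS release, a multiple of the −log10 of a p-value, but no header states this. The 2 H3K27me3 lists have the broadPeak layout. By that layout their deposited columns hold a score, a fold enrichment over a control library, and −log10 of a p-value and of a q-value, all as the authors' caller gave them. The smallest −log10 q was 1.00 in both lists. All these values are the authors' own and served only to describe, rank or filter peaks within a list.

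Peaks on the 22 autosomes were analysed, and touching peaks were merged. The plan had included chromosome X. It was left out to keep donor-level information out of the results. Overlaps were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with exact (Clopper-Pearson) binomial 95% intervals and rank correlations from scipy 1.17.1 and plots from matplotlib 3.10.9. The plan had named another overlap tool. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. The chance level came from 100 random circular shifts of the peaks along their chromosomes. The intervals cover counting error only, neighbouring peaks are not independent, and no replicate error can be given. The overlap code was tested on simulated lists on 22 chromosomes and recovered 7 of 7 known quantities, with a tolerance of 15% for the shifted level.

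H3K4me1 regions were classed by overlap of at least 1 bp with H3K27Ac and H3K27me3 of the same cell type. The H3K4me1 peaks of both cell types were merged to compare classes region by region. A merged region took its class in a cell type from marks anywhere in it, also outside that cell type's own H3K4me1 peak. H3K27Ac peaks of both cell types were joined over gaps of up to 10 kb, and a joined region counted as different when its covered bases differed by at least 2-fold and at least 5 kb. Each list was also divided into 4 equal groups by the deposited score, or by −log10 p for H3K27me3.

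The gene table at hand names another assembly (GRCh38) than the files, so no hg19 gene annotation was used here. Regions are given by position only, start sites were not removed from the H3K4me1 regions, and the planned gene lists were not tested. The rule for this case, set in advance, named the 10 joined regions with the largest excess of H3K27Ac-covered bases in each cell type and the 10 longest regions active in 1 cell type and poised in the other. Regions chosen otherwise are identified as such.

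Each result was also computed, where it applied, with coverage of at least 50%, merging of peaks within 1 kb, the higher-scoring 50% of each list, equal numbers of top-scoring peaks, or gaps of 5 or 20 kb, all set before the data were examined. Equal covered length, scaling of covered bases to equal totals, and shifted levels for H3K27me3 peaks by width and for regions with H3K4me1 in 1 cell type alone were added after the data had been seen. How the Tfh share of covered bases followed H3K27Ac density was tested in 1 Mb windows, with Spearman's rho within each chromosome and 1000 resamplings of chromosomes. A longer list can come from deeper sequencing, a better immunoprecipitation or more marked chromatin, and peak lists without read counts do not separate these. A difference in a peak's presence is therefore a difference in calling, not a measured difference in signal.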

Results

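The series mapped 3 histone modifications by ChIP-seq in CD4 T cells sorted from human tonsil. T follicular helper (Tfh) cells, the CD4 cells that help B cells in germinal centres, were sorted as CD45RA-negative cells with high PD-1, high CXCR5 and low PSGL-1. The comparison population, non-Tfh effector (Teff) cells, had low PD-1, low CXCR5 and high PSGL-1. H3K4me1 is found at enhancers and around promoters, H3K27Ac at active enhancers and promoters, and H3K27me3 in chromatin repressed by Polycomb. Each of the 6 combinations of cell type and mark had 1 library and 1 peak list. A library labelled TI was sequenced for each cell type and has no list used here. With no replicates, no difference between Tfh and Teff was tested, and the intervals given cover counting error only. The read depth behind the lists is unknown, because the lists hold peaks and scores and no read counts. Values for lists of equal covered length or scaled to equal totals, the shifted levels by width and the levels for regions with H3K4me1 in 1 cell type alone were computed after the data had been seen.

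On the 22 autosomes, the Tfh lists were longer than the Teff lists for every mark. The H3K27Ac lists held 163532 peaks in Tfh and 149060 in Teff. The H3K4me1 lists held 63684 and 48113 peaks, and the H3K27me3 lists 192996 and 147717. Covered bases followed with different ratios. H3K27Ac peaks covered 209.6 Mb in Tfh and 171.6 Mb in Teff, a ratio of 1.22. H3K4me1 peaks covered 131.1 Mb and 121.7 Mb, a ratio of 1.08, and the mean peak was 2530 bp wide in Teff and 2058 bp in Tfh. H3K27me3 peaks covered 243.8 Mb and 143.1 Mb, a ratio of 1.70. The mean width was 1281 bp in Tfh and 1151 bp in Teff for H3K27Ac, and 1263 bp and 969 bp for H3K27me3. The median fold enrichment of the H3K27me3 peaks, as given by the authors, was 2.73 in Tfh and 2.84 in Teff. Their −log10 q was under 2 for 65.1% of the Tfh and 73.8% of the Teff peaks.

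The design set out to compare the enhancer maps of the sorted populations, and the first question was how much of each map the populations had in common. Tfh and Teff shared most of their acetylated sites. Of the Tfh H3K27Ac peaks, 63.3% (exact binomial 95% interval 63.1 to 63.5) overlapped a Teff peak by at least 1 bp. Of the Teff H3K27Ac peaks, 75.6% (75.3 to 75.8) overlapped a Tfh peak. Peaks moved along their chromosomes 100 times overlapped in 13.3% of the Tfh cases and 15.4% of the Teff cases on average. At the level of bases, 135 Mb were acetylated in both lists, 74.3 Mb in the Tfh list alone and 36.3 Mb in the Teff list alone. The intersection was 0.550 of the union. With the Tfh list reduced to its top-scoring peaks up to the covered length of the Teff list, the order turned: 79.3% of Tfh peaks and 64.6% of Teff peaks were shared. The reduced list held 107296 Tfh peaks against 149060 Teff peaks. Removing Tfh peaks cannot raise the Teff share, and the peaks removed were low-scoring ones, which are less often shared. The turn is therefore not evidence about the cell types.

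**Figure D1:**
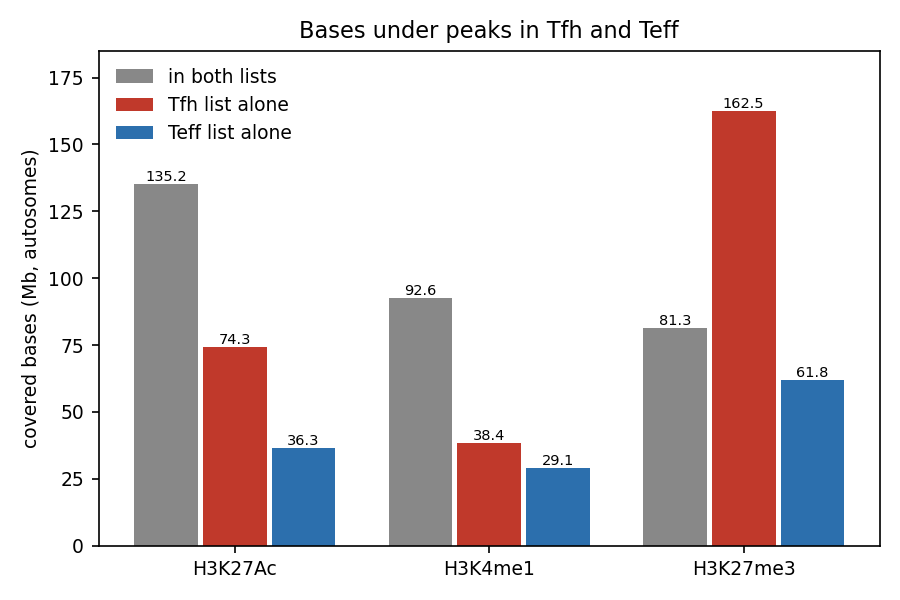
Bases under peaks on the autosomes (Mb, linear axis from 0) for each mark, split into bases in both lists, in the Tfh list alone and in the Teff list alone, with 1 library per list. For H3K27Ac and H3K4me1 the bases in both lists form the tallest bar, and for H3K27me3 the tallest bar is the 162.5 Mb in the Tfh list alone.

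H3K4me1 sites, with promoters not set aside, were also mostly common to both cell types. Of the Teff H3K4me1 peaks, 85.6% (85.3 to 85.9) overlapped a Tfh peak, and of the Tfh peaks 66.3% (65.9 to 66.6) overlapped a Teff peak. The shifted levels were 9.07% and 7.34%. The lists had 92.6 Mb in common, with 38.4 Mb in Tfh alone and 29.1 Mb in Teff alone, and the intersection was 0.578 of the union. With equal numbers of top-scoring peaks the shares came together, at 77.8% of Tfh and 78.8% of Teff peaks.

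H3K27me3 was the least shared mark in the lists as called. Its lists have another layout and score than those of the other marks, so the marks are not compared at a like threshold. For H3K27me3, 36.9% (36.7 to 37.1) of the Tfh peaks and 53.4% (53.1 to 53.7) of the Teff peaks overlapped a peak of the other cell type. The shifted levels were 10.24% and 13.8%. The lists had 81.3 Mb in common, Tfh alone held 162.5 Mb, Teff alone held 61.8 Mb, and the intersection was 0.266 of the union. Here too the order of the shares turned when the Tfh list was reduced to the covered length of the Teff list, to 52.5% of Tfh and 33.1% of Teff peaks. The same limit holds, with 77377 Tfh peaks left against 147717 Teff peaks. The widest H3K27me3 domains, of 20 kb or more, were largely common to both. They were few, with 313 peaks over 9.08 Mb in Tfh and 119 over 3.44 Mb in Teff. In peaks of 20 kb or more, 77.2% of the Tfh bases and 97.9% of the Teff bases were covered by the other list, against shifted levels of 5.29% and 9.26%. In peaks of 5 to 20 kb the shares were 56.3% and 91.2%, against 5.03% and 9.29%. In peaks under 1 kb the shares were 18.8% and 35.3%, against 5.04% and 8.36%. The longest domain lay on chromosome 12 (hg19, 54316765 to 54460305). It spanned 144 kb in Tfh, and the Teff list covered 142 kb of it. The next Tfh domains were on chromosome 2 (176943067 to 177057667), where Tfh covered 115 kb and Teff 114 kb, and on chromosome 17 (46653061 to 46726642), where Tfh covered 73.6 kb and Teff 73.2 kb.

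Peaks with high scores were shared far more often than peaks near the calling threshold. Each list was divided into 4 equal groups by score. In the group with the highest scores, 98.3% of Tfh and 99.4% of Teff H3K27Ac peaks were shared. In the group with the lowest scores the shares were 29.9% and 47.8%. For H3K4me1 they went from 96.4% to 30.7% in Tfh and from 99.3% to 65.6% in Teff. For H3K27me3 they went from 59.0% to 21.7% in Tfh and from 64.9% to 42.3% in Teff. Peaks found in 1 cell type alone were also narrower. Their median width for H3K27Ac was 696 bp in Tfh and 607 bp in Teff, against 1184 bp and 971 bp for shared peaks.

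**Figure D2:**
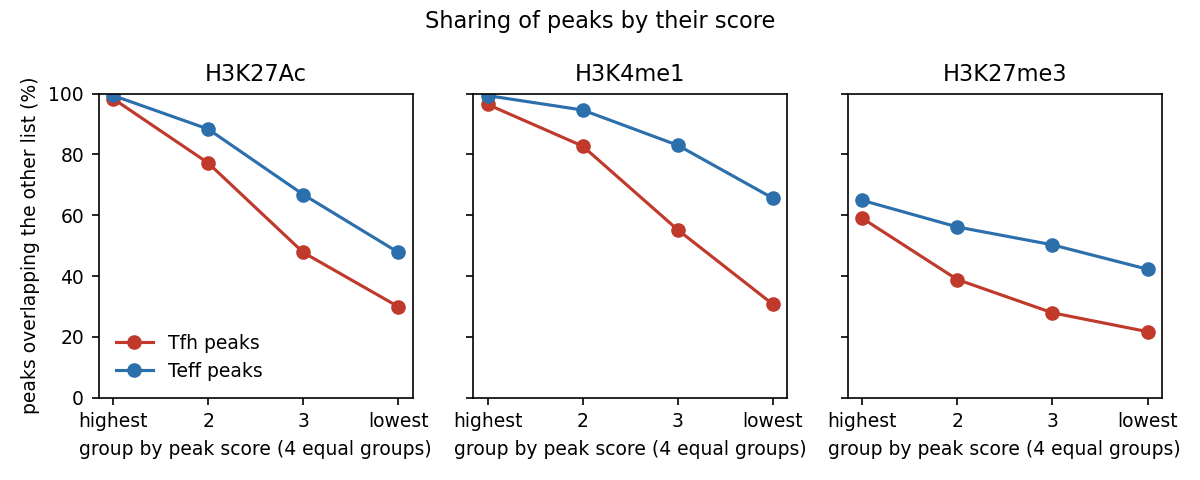
Percent of peaks that overlap a peak of the other cell type (vertical axis, linear) in each of 4 equal groups of a list, ordered from the highest to the lowest score (horizontal axis), for Tfh and Teff lists of the 3 marks. Sharing of H3K27Ac goes from 98.3% and 99.4% in the highest group to 29.9% and 47.8% in the lowest. H3K27me3, whose lists are scored in another way, starts at 59.0% and 64.9%.

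The Tfh and Teff lists differed unevenly along the genome, and the marks did so in different ways. The ratio of H3K27Ac-covered bases, Tfh over Teff, was similar on every autosome, from 1.15 on chromosome 19 to 1.32 on chromosome 18. The H3K4me1 ratio went from 0.621 on chromosome 19 to 1.46 on chromosome 4. The H3K27me3 ratio took the opposite course, from 0.997 on chromosome 4 to 3.80 on chromosome 16, with 3.59 on chromosome 20 and 3.44 on chromosome 22.

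**Figure D3:**
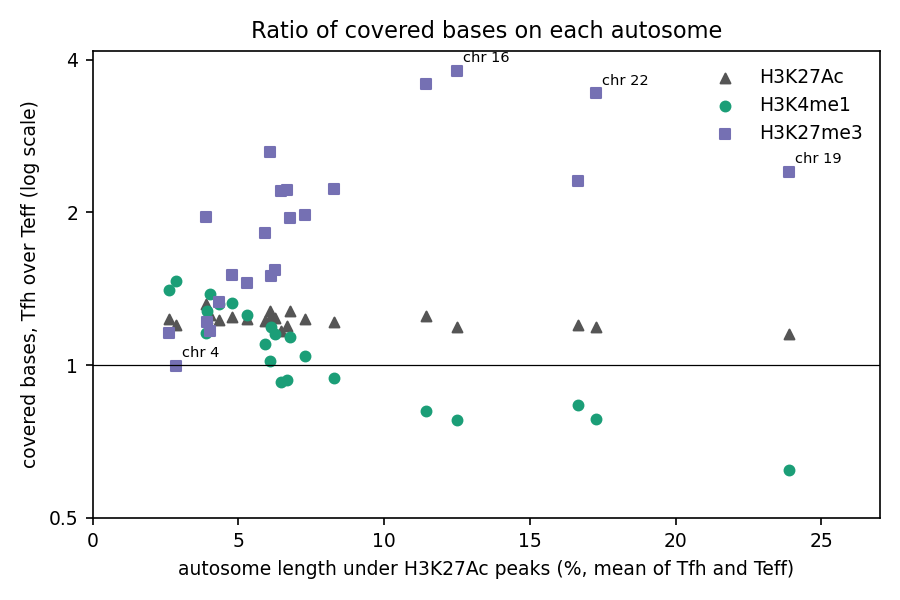
Ratio of covered bases, Tfh over Teff (vertical axis, log scale), on each of the 22 autosomes for 3 marks, against the percent of the autosome under H3K27Ac peaks (horizontal axis, mean of both cell types). H3K27Ac stays between 1.15 and 1.32, H3K4me1 is lowest at 0.621 on chromosome 19, and H3K27me3 reaches 3.80 on chromosome 16.

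The study described active, intermediate and poised enhancers. Here an H3K4me1 region was called active with H3K27Ac and no H3K27me3, poised with H3K27me3 and no H3K27Ac, and intermediate with neither. Promoters could not be set aside, so the regions include those at transcription start sites. Tfh cells had 24094 active regions and Teff cells 22013. The Tfh list had many more intermediate regions, 25388 against 12791. Poised regions were few, 3193 in Tfh and 2377 in Teff. A further 11009 Tfh and 10932 Teff regions carried both H3K27Ac and H3K27me3. With equal numbers of peaks the order turned for active (21721 and 22013), poised (1728 and 2377) and both-mark regions (8695 and 10932), and stayed for intermediate ones.

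As a share of H3K4me1 regions, active regions made up 37.8% (37.5 to 38.2) in Tfh and 45.8% (45.3 to 46.2) in Teff. Intermediate regions made up 39.9% (39.5 to 40.2) and 26.6% (26.2 to 27.0). Poised regions made up 5.01% (4.85 to 5.19) in Tfh and 4.94% (4.75 to 5.14) in Teff, with overlapping intervals. The poised share was lower in Tfh in each of the other settings tried, from 3.21% against 3.37% in the higher-scoring 50% of each list to 3.33% against 4.94% with equal covered length. Regions with both marks made up 17.3% (16.99 to 17.6) and 22.7% (22.3 to 23.1). Active regions were wider than intermediate ones, with medians of 2026 bp against 1141 bp in Tfh and 2265 bp against 1451 bp in Teff. With equal numbers of top-scoring peaks for each mark, active regions made up 45.1% in Tfh and 45.8% in Teff, and the Tfh intermediate regions numbered 15969. The active share was also lower in Tfh in the other settings. It was 28.3% against 32.8% with 50% coverage, 49.0% against 54.6% in the higher-scoring 50%, and 42.2% against 45.8% with equal covered length. H3K27Ac overlapped H3K4me1 regions, by at least 1 bp, more often than shifted regions, at 55.1% against 16.05% in Tfh and 68.5% against 16.3% in Teff. The excess of H3K27me3 over the shifted level was smaller in Tfh than in Teff. It was 22.3% against a shifted 19.8% (range of 100 shifts 18.8 to 20.9) in Tfh, and 27.7% against 14.9% (13.8 to 16.2) in Teff. Shifts along whole chromosomes do not keep the local density of marks, and no local level is given here. The small Tfh excess may therefore not exceed a local level. In the crossed pairs, Teff H3K27me3 overlapped 22.7% of the Tfh H3K4me1 regions against a shifted 13.8%, and Tfh H3K27me3 overlapped 30.1% of the Teff regions against 21.97%.

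**Figure D4:**
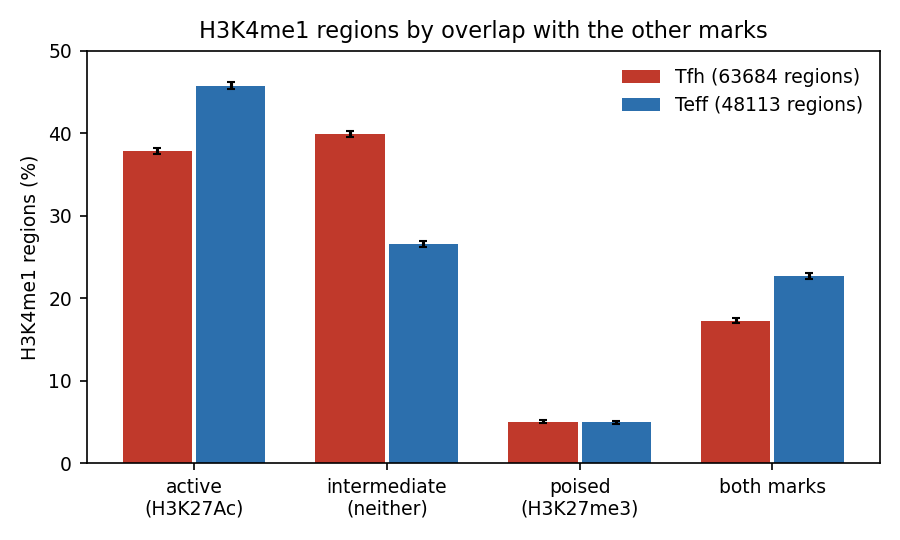
Percent of H3K4me1 regions (vertical axis, linear from 0) that are active, intermediate, poised or marked by both H3K27Ac and H3K27me3, in Tfh and Teff, with exact binomial 95% intervals as error bars and 1 library per list. Intermediate regions are 39.9% in Tfh and 26.6% in Teff, and poised regions are 5.01% and 4.94%.

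Merging the H3K4me1 peaks of both cell types gave 65363 regions. The class in a cell type counts marks anywhere in the merged region, also outside that cell type's own H3K4me1 peak. H3K4me1 was present in both at 36964 of them, in Tfh alone at 21483 and in Teff alone at 6916. The Tfh-alone excess depends on the peaks kept. Sharing of H3K4me1 peaks was 77.8% in Tfh and 78.8% in Teff with equal numbers, and 74.6% and 81.4% with equal covered length. Where both cell types had H3K4me1, 76.2% of the regions were in the same class. In all, 13993 regions were active in both, 6934 were active in Tfh and not in Teff, and 6331 were active in Teff and not in Tfh. Not active does not mean without H3K27Ac, since it includes regions with both marks or with no H3K4me1 call in that cell type. Of the active regions, 1745 in Tfh were intermediate in Teff and 913 in Teff were intermediate in Tfh. A further 16092 regions were intermediate in Tfh and without H3K4me1 in Teff, against 2109 the other way round. Among regions active in 1 cell type, 3297 active in Tfh had no H3K4me1 in Teff and 3060 active in Teff had none in Tfh, while 1725 and 2205 carried both lysine 27 marks in the other cell type. Direct exchange between active and poised was rare: 167 regions were active in Tfh and poised in Teff, and 153 were the reverse. With only the higher-scoring 50% of each list the order turned, to 28 and 42, while equal numbers of peaks gave 160 and 100 and equal covered length 120 and 59.

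Regions with H3K4me1 in Tfh alone were mostly without acetylation. Of these, 18.4% (17.9 to 18.9) carried H3K27Ac in Tfh and 11.95% (11.5 to 12.4) did in Teff. The ratio of these shares was 1.54, against 1.19 (1.15 to 1.24) for the same regions shifted, and 1.05 with H3K27Ac lists of equal covered length. Equal covered length removes peaks from the Tfh list alone, so it can only lower the Tfh shares given in this paragraph. Of the regions with H3K4me1 in Teff alone, 62.7% (61.5 to 63.8) carried H3K27Ac in Teff and 62.0% (60.8 to 63.1) in Tfh. Their ratio, Teff over Tfh, was 1.01, against 0.862 (0.827 to 0.904) shifted, and 1.17 with equal covered length. H3K27me3 lay on 36.7% (35.6 to 37.9) of these Teff-alone regions in Tfh and on 25.3% (24.2 to 26.3) in Teff, a ratio of 1.45 against 1.70 (1.48 to 1.97) shifted, and of 1.001 with equal covered length. On Tfh-alone regions it lay on 9.75% in Tfh and 12.3% in Teff, a ratio of 0.796 against 1.39 (1.298 to 1.52) shifted, and of 0.410 with equal covered length. On regions with H3K4me1 in both it lay on 32.2% and 31.3%, a ratio of 1.03 against 1.42 (1.36 to 1.48) shifted, and of 0.754 with equal covered length. Regions with H3K4me1 in both were acetylated at 75.5% in Tfh and 73.1% in Teff. That ratio was 1.03, against 1.15 (1.13 to 1.18) shifted, and 0.955 with equal covered length.

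Of the 10 longest regions that were active in one cell type and poised in the other, 9 were active in Tfh. The longest, on chromosome 6 (39221192 to 39236547), had 7.06 kb of H3K27Ac in Tfh and none called in Teff, where 0.460 kb of H3K27me3 was called. A pair of these regions lay on the long arm of chromosome 3. The one at 187682440 to 187695142 had 5.15 kb of Tfh H3K27Ac and 12.7 kb of Tfh H3K4me1, against 5.30 kb of H3K4me1 and 0.658 kb of H3K27me3 in Teff. The one at 188415495 to 188428338 had 2.37 kb of Tfh H3K27Ac and 0.433 kb of Teff H3K27me3. On chromosome 16 (79638930 to 79650350), Tfh had 3.07 kb of H3K27Ac and Teff 0.531 kb of H3K27me3. The single region active in Teff was on chromosome 2 (134987326 to 134998226), with 2.004 kb of Teff H3K27Ac and 0.197 kb of Tfh H3K27me3. The poised call in these 5 regions rests on less than 1 kb of H3K27me3 each, which need not touch the H3K4me1 peak of that cell type. None of the 10 kept both classes when at least 50% of the region had to be covered.

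H3K27Ac and H3K27me3 modify the same lysine, and their peaks overlapped within each cell type. H3K27me3 covered 21.8% of the H3K27Ac bases in Tfh, 2.26 times the shifted level of 9.60% (8.52 to 10.5). In Teff it covered 11.7%, 2.39 times the shifted 4.89% (4.30 to 5.42). Relative to the shifted level, the pairing of cell types made little difference. Tfh H3K27me3 covered 21.8% of the Teff H3K27Ac bases, 2.28 times the shifted level, and Teff H3K27me3 covered 11.1% of the Tfh H3K27Ac bases, also 2.28 times. H3K27me3 found in Tfh alone covered 14.8% of the bases acetylated in Tfh alone and 14.6% of those acetylated in Teff alone. H3K27me3 found in Teff alone covered 2.29% and 2.47%.

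Clusters of acetylated peaks were compared after joining H3K27Ac peaks over gaps of up to 10 kb, which gave 42029 regions. A region counted as different when its covered bases differed by at least 2-fold and 5 kb. By this rule 229 regions had more H3K27Ac in Tfh and 4 had more in Teff. Scaling both lists to equal totals gave 79 and 10, and reducing the Tfh list to the covered length of the Teff list gave 40 and 34. Of the 229 regions, 224 had more H3K27Ac in Tfh with the reduced list and 42 met the rule again in the same interval, as did the 4 Teff regions. In the higher-scoring 50% of each list, 83 of the 229 and 1 of the 4 met it again, while the rule called 307 joined regions in Tfh and 3 in Teff. With equal numbers of peaks it called 153 and 10.

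The 10 regions with the largest excess in Tfh were long, densely acetylated stretches in which neither cell type lacked the mark. The largest excess was on chromosome 19 (18155023 to 19781934), with 912 kb covered in Tfh and 834 kb in Teff, a ratio of 1.09, below the 1.22 of the whole lists. With equal covered length its excess was 17.1 kb in place of 78.5 kb. The chromosome 1 stretch (9144472 to 10026550) had 382 kb in Tfh and 307 kb in Teff, a ratio of 1.24. The region closest to the rule lay on chromosome 3 (194751145 to 194949941), with 125.7 kb in Tfh and 63.3 kb in Teff, a ratio of 1.99. It had 90.3 kb of H3K4me1 in Tfh and 44.9 kb in Teff. Its excess of 62.4 kb was 56.8 kb with equal covered length, then the largest of the 10, and 74.0 kb in the higher-scoring 50% of the lists, where it met the rule. None of the 10 met the rule in the full lists.

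Among the 10 regions with the largest excess in Teff, 1 met the rule. It lay on chromosome 1 (167586651 to 167695204), with 26.7 kb of H3K27Ac in Teff and 12.5 kb in Tfh, a ratio of 2.13, and with 53.9 kb against 40.4 kb of H3K4me1. In the higher-scoring 50% of each list the Tfh-minus-Teff difference was -5.13 kb in place of -14.2 kb, and the rule was no longer met. The largest excess, on chromosome 1 (25971376 to 26165138), was 29.7 kb, with 88.8 kb in Teff and 59.1 kb in Tfh. In that region Tfh also had 75.9 kb of H3K27me3 against 1.93 kb in Teff, and Teff had 80.3 kb of H3K4me1 against 40.0 kb. On chromosome 20 (47208937 to 47445526) Teff had 117 kb of H3K27Ac against 103.8 kb in Tfh, and 84.0 kb of H3K4me1 against 24.6 kb. On chromosome 5 (131745821 to 131838721) Teff had 50.7 kb of H3K27Ac against 40.6 kb.

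Only 5625 of the 42029 joined regions had 5 kb or more covered in either list and could meet the rule, so regions that met it are long by construction. The 229 Tfh regions that met the rule had a median span of 40.5 kb, against 1.60 kb for all joined regions. The 5 with the largest excess in Tfh and all 4 in Teff are described, a choice made after their values were seen. The largest Tfh excess among them was on chromosome 12 (112841784 to 112975183), with 52.2 kb of H3K27Ac in Tfh and 15.8 kb in Teff, a ratio of 3.30. H3K4me1 covered 61.3 kb there in Tfh and 24.1 kb in Teff. The chromosome 1 region at 235708512 to 235823072 had 50.2 kb and 14.8 kb, a ratio of 3.40. The chromosome 15 region at 69882850 to 69989573 had 48.0 kb and 13.3 kb, a ratio of 3.61, with 79.9 kb of H3K4me1 in Tfh and 24.9 kb in Teff. On chromosome 11 (47996679 to 48132182) the values were 64.2 kb and 30.9 kb, a ratio of 2.08, with H3K4me1 at 94.98 kb and 89.0 kb. Elsewhere on chromosome 11 (93191212 to 93278851) they were 38.04 kb and 9.24 kb, a ratio of 4.12. All 5 met the rule again in the higher-scoring 50% of each list and with equal numbers of peaks. The chromosome 11 region at 47996679 did not with equal covered length, and of the 10 largest Tfh regions 7 did. The other 3 Teff regions were on chromosome 12 (65062160 to 65108124), with 9.75 kb in Teff and 2.18 kb in Tfh, on chromosome 15 (63884013 to 63905086), with 11.9 kb and 5.64 kb, and on chromosome 3 (71463123 to 71496001), with 8.79 kb and 3.09 kb.

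**Figure D5:**
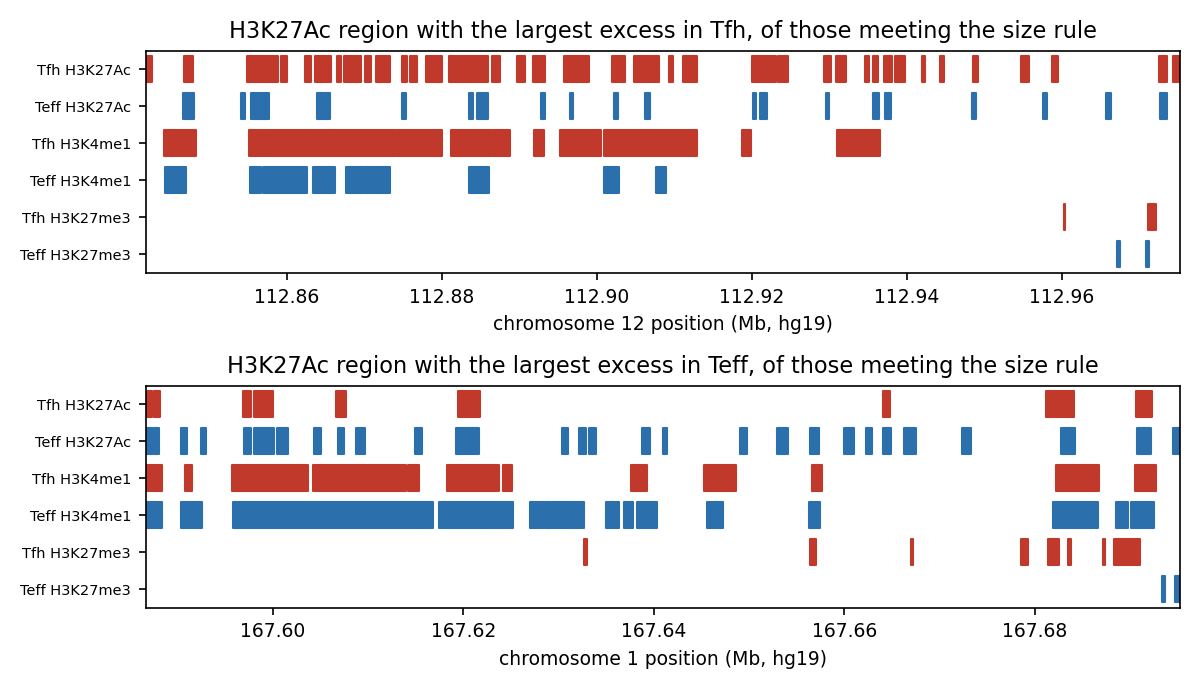
Peaks of the 3 marks in Tfh and Teff (bars, to scale) across the region with the largest H3K27Ac excess in each cell type among those that met the size rule, on chromosome 12 and chromosome 1 (horizontal axis, hg19 position in Mb). Tfh covers 52.2 kb of the chromosome 12 region with H3K27Ac and Teff 15.8 kb, while Teff covers 26.7 kb of the chromosome 1 region and Tfh 12.5 kb.

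H3K4me1 often differed the same way as H3K27Ac in these regions. Of the 229 regions with more H3K27Ac in Tfh, 112 had more H3K4me1 in Tfh, 58 had more in Teff and 59 were equal. Over all 42029 regions the numbers were 6602, 7048 and 28379. Most of those regions had too few covered bases to meet the rule, so the 2 sets are not matched for size. In all 4 regions with more H3K27Ac in Teff, H3K4me1 also covered more in Teff and H3K27me3 covered more in Tfh. H3K27me3 covered more in Tfh at 143 of the 229 and more in Teff at 41, against 15844 and 5874 over all regions.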

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

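Equal covered length and scaling to equal totals were chosen after the data had been seen. Equal covered length removed low-scoring peaks from the Tfh lists alone, so its turned order of shared peaks is not evidence about the cell types. The order of Tfh and Teff turned in 9 of 44 comparisons under an alternative: shared H3K27Ac and H3K27me3 peaks with equal covered length, active regions with equal numbers (21721 and 22013), poised regions with equal numbers and equal covered length, regions with both marks in these settings (8695 and 10932 with equal numbers) and in the higher-scoring 50%, and active-to-poised exchange in the higher-scoring 50%. For regions with H3K4me1 in both cell types, the Tfh-over-Teff ratio of acetylated shares turned from 1.03 to 0.955 with equal covered length. The same ratio for H3K27me3 turned from 1.03 to 0.754. Equal covered length can only lower both ratios, so these turns are not evidence about the cell types. Of the values that answer a comparison, 61 moved past their tolerance and 31 stayed within it. The tolerance is the 95% counting interval for a share and 1.5 times for a count, so counts within it can still differ widely. No replicates exist, so no library could be left out, and the unknown read depth limits every comparison of list length. No paired analysis was possible because each cell type and mark has 1 library. Distances of 1 and 5 kb from start sites, H3K27Ac regions outside 2 kb of start sites, all gene-list alternatives and the setting with chromosome X were not run. The cause of the changes given here was not tested, beyond fewer peaks entering the stricter settings.

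Shares of peaks in common are given for Tfh and then Teff. With at least 50% of the peak covered, they were 58.5% and 72.8% for H3K27Ac, 63.4% and 80.6% for H3K4me1, and 21.7% and 40.6% for H3K27me3. With peaks within 1 kb merged, they were 61.9% and 73.5%, 69.9% and 86.2%, and 37.5% and 52.7%. In the higher-scoring 50% they were 70.1% and 82.5% for H3K27Ac, 66.8% for Tfh H3K4me1, and 32.4% and 46.2% for H3K27me3. With equal numbers they were 66.8% and 73.3%, 77.8% and 78.8%, and 41.6% and 47.2%. With equal covered length they were 79.3% and 64.6%, 74.6% and 81.4%, and 52.5% and 33.1%.

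In the higher-scoring 50%, Tfh had 15589 active, 9531 intermediate and 1021 poised regions and 5701 with both marks, and Teff had 13135, 4271, 810 and 5840. With 50% coverage, 7181 Tfh and 6082 Teff regions had both marks and 23712 Teff regions were intermediate. With equal numbers Tfh had 15969 intermediate and 1728 poised regions. With equal covered length Tfh had 1742 poised regions and 7290 with both marks. Regions active in both numbered 9084 with 50% coverage. Those active in Tfh and poised in Teff numbered 99 with 50% coverage and 28 in the higher-scoring 50%. Those active in Teff and poised in Tfh numbered 93 and 42 in these settings, 100 with equal numbers and 59 with equal covered length.

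H3K27me3 covered 16.3% of Tfh and 9.96% of Teff H3K27Ac bases in the higher-scoring 50%, and 19.7% and 14.9% of the Tfh bases with equal numbers and equal covered length. Joined regions with more H3K27Ac numbered 79 in Tfh and 10 in Teff after scaling, and 40 and 34 with equal covered length. The Teff count was 8 with a 5 kb gap and 10 with equal numbers. Of the 10 longest switching regions, 10 kept their classes with equal numbers, 7 with equal covered length, 3 in the higher-scoring 50% and 0 with 50% coverage.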

Other observations

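The test of H3K27me3 by cell type, the tests of the Tfh share against acetylation density, and the shifted and equal-length levels for H3K4me1 regions were chosen after the result was seen. H3K27me3 peaks of 5 kb or more held more acetylation than narrower ones. In Tfh, H3K27Ac covered 12.7% of the bases in H3K27me3 peaks under 1 kb, 28.4% in peaks of 5 to 20 kb and 30.7% in longer ones, which was 1.70, 3.11 and 3.36 times the shifted level. In Teff the shares were 6.79%, 29.4% and 28.7%, or 1.25, 4.27 and 4.29 times. From the narrowest to the widest peaks, H3K4me1 went from 2.68% to 23.5% in Tfh and from 4.08% to 45.0% in Teff. Within the 144 kb domain on chromosome 12, H3K27Ac covered 29.0 kb in Tfh and 24.4 kb in Teff, and H3K4me1 covered 43.7 kb and 56.5 kb.

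The Tfh-to-Teff ratio of H3K27me3 coverage differed between chromosomes, from 0.997 on chromosome 4 to 3.80 on chromosome 16. The larger number of Tfh peaks is argued against as the whole cause. The SD of the log2 ratio over autosomes with equal numbers of peaks was 1.06 times that with all peaks. Covered length was not made equal for this SD. A difference between the libraries that follows acetylation density stays open: within chromosomes, the Tfh share of the bases covered in 1 Mb windows rose with density at a median Spearman rho of 0.335 (0.160 to 0.446), an interval that spans the bound of 0.2 set for such a difference. With equal numbers of peaks rho was 0.442 (0.301 to 0.567) and with equal covered length 0.554 (0.332 to 0.591), both past the bound, although equal covered length also gave 0.370 for H3K27Ac, whose ratio hardly differed between chromosomes. A gain of H3K27me3 in Tfh where Teff is acetylated cannot be told apart from no such gain: Tfh-only H3K27me3 covered Teff-only H3K27Ac 0.986 times as much as Tfh-only H3K27Ac (0.965 to 1.01 over 1000 resamplings of chromosomes).

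The H3K4me1 ratio differed between chromosomes in the opposite order, from 0.621 on chromosome 19 to 1.46 on chromosome 4. With equal numbers of peaks the SD of the log2 ratio was 0.940 of that with all peaks, which argues against the number of peaks as the whole cause. Covered length was not made equal here either. The Tfh share in 1 Mb windows fell with acetylation density within chromosomes, with a median rho of -0.308 (-0.444 to -0.201) against a bound of -0.2. A library difference that follows density would give this. The intervals with equal numbers (-0.370 to -0.142) and with equal covered length (-0.379 to -0.170) span the bound. Regions with H3K4me1 in Tfh alone carried H3K27Ac 1.54 times as often in Tfh as in Teff, above the shifted 1.19 (1.15 to 1.24). The ratio was 1.05 (1.001 to 1.104) with H3K27Ac lists of equal covered length. That setting removes Tfh peaks alone and can only lower the ratio, so the drop does not decide between causes. A difference between the cell types and one between the libraries both stay open. With 1 library per cell type the windows cannot separate them, and a difference between the cell types was not tested by chromosome.

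H3K27me3 overlapped Tfh H3K27Ac more than shifted peaks did. A shared location in the same megabase-scale parts of the chromosomes is argued against as the whole cause, because the overlap was 1.34 times that with the H3K27Ac peaks moved by 200 kb. The moved level of 16.3% was still above the shifted 9.60%, so it may account for part. Low-scoring H3K27me3 calls within the list are argued against as the main source of the excess over the shifted level. The observed-over-shifted share of peaks with H3K27Ac in the highest of 4 equal score groups was 1.09 times that in the lowest. That highest group reached down to a −log10 p of 4.00, so weak calling across the whole list stays open. The level moved by 200 kb is not given by score group, so the source of the excess over that level stays open too. The pairing of cell types made little difference to the excess over the shifted level. That excess was 2.26 times within Tfh and 2.28 times for Teff H3K27me3 on Tfh H3K27Ac. Against the level moved by 200 kb, the excess differed with the H3K27me3 list. It was 1.34 and 1.33 times for Tfh H3K27me3 on Tfh and Teff H3K27Ac, and 1.56 and 1.62 times for Teff H3K27me3. No biological explanation was tested, and a mixture of cells or alleles stays open.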
